A study of Homo sapiens with 6 samples.

How the data were processed

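NCI-H460 is an established human cell line from a large cell carcinoma of the lung. Per the labels, a population rich in cancer stem cells (CSC-rich) was obtained from it by growth as spheroids, and the parental cells (wild type) were kept beside it; serum was added for the parental culture alone, so medium and population cannot be told apart. Each population was left untreated, treated with a scramble control, or treated with an agent that the labels name PNAs-A15, for 6 h. What the code name stands for is not given in the sources used here. The label of the treated CSC-rich array names the agent in a shortened form and was taken to mean the same agent. Total RNA was amplified to biotinylated cRNA and hybridised to Illumina HumanHT-12 v4 BeadChips. The design has 6 groups with 1 array in each, 3 arrays per population, and no replicate of any group.

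The deposited table holds, for each of 47323 probes and each array, a linear signal intensity and a detection p-value, which states how the probe's signal ranks among the array's negative controls. Per the submitters' processing notes, GenomeStudio 2011.1 was used; further steps are not given in the sources used here. The intensity values in the deposited series matrix equalled those of the table in 100% of cells, so they were linear, not centred and not normalized between arrays; they served as the unnormalized alternative. The median signal of an array lay between 129.8 and 151.6.

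Probes were named through a platform annotation table: 30113 had 1 gene symbol, 8 had several and were left unnamed, and 17202 were not listed and stay unnamed here. Gene identifiers of 30074 named probes matched an NCBI RefSeq gene table of GRCh38.p14, used for names only, which changed 0 symbols. No coordinates are given, since no genome build is named in the sources used here.

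Signals were background-corrected with the normal-exponential model of limma's neqc (limma 3.58.1 in R 4.3.3), with the background of negative controls inferred from the detection p-values and an offset of 16, then quantile-normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 2 of the 6 arrays were kept (16023 probes). The probe with the highest mean over the arrays stood for its gene, which left 12101 genes. A probe detected on no array of a group has only a bound there; where it was detected on some arrays of a group, their number is given. Its fold is then given as "at least N-fold", from the brighter group's mean and, for each dim array, the higher of the lowest signal among detected probes and the probe's own.

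The comparisons were CSC-rich against parental cells, PNAs-A15 against scramble, scramble against untreated control, and PNAs-A15 against untreated control. With 1 array per group, p-values come only from limma's additive model of treatment and population over the 6 arrays, which leaves 2 residual degrees of freedom. The spread in that model holds array noise and any difference of the treatment effects between populations together. Where nothing says that arrays came from separate cultures, the p-values measure only the spread between these arrays. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Differences between 2 single arrays were described by counts of genes at least 2-fold apart, without a test.

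Gene lists (30) for pathways, stem cell and lineage markers and markers of other cell types were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list (median 0.030), adjusted over the 29 lists with at least 3 measured members. The second form rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. For single arrays, a list's median was placed among the medians of 10000 random lists of the same size matched on mean level in 10 bins. The genes named in the text also followed a rule fixed before the data were examined. For CSC-rich against parental cells these were the 12 highest and 12 lowest genes past the threshold with the same sign in all 3 treatment pairs. For PNAs-A15 against scramble or control they were the 10 highest and 10 lowest by the smaller of the 2 populations' differences among genes of the same sign in both. For scramble against control they were the 5 highest and 5 lowest of that kind, and for PNAs-A15 against scramble in each population alone the 5 highest and 5 lowest. Up to 4 members of each list with the largest differences were added, and 7 stem cell genes (PROM1, CD44, SOX2, NANOG, POU5F1, ABCG2 and ALDH1A1) always. Open reading frames and clone names without an official symbol were not named.

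The scripts were tested on simulated data in which 200 of the 12101 genes were changed between populations and 200 others by PNAs-A15. The noise was drawn independently for each gene, without an outlying array, so the rates below need not hold for these arrays. For CSC-rich against parental cells, changes of 1, 2, 3 and 4 on the log2 scale were recovered in 4%, 72%, 100% and 100% of genes, with 16 false calls. For PNAs-A15 against scramble, recovery was 2%, 58%, 90% and 100%, with 11 false calls. In a camera test for CSC-rich against parental cells, a shifted list of 20 genes was called, as was 1 unshifted list. Alternatives covered the background correction, the normalization, the probe filter, the choice of probe, the variance model, the covariates and leaving out each array. The number of arrays limits the precision.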

Results

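Gene expression was measured on 6 arrays, 1 each of untreated, scramble-treated and PNAs-A15-treated cells, in parental NCI-H460 lung carcinoma cells and in the CSC-rich population grown from them as spheroids. No group had a replicate. Between 36.5% and 42.8% of the 47323 probes had a detection p under 0.05 on an array. The lowest share came from the parental PNAs-A15 array, followed by the CSC-rich scramble array at 38.5%. Across genes, the parental PNAs-A15 array correlated with the others at a Pearson r of 0.828 to 0.871, whereas the other 5 arrays correlated among themselves at 0.912 to 0.992. The first principal component held 60.7% of the variance.

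The first comparison asked how the CSC-rich population differed from the parental cells. Genes of mitosis were far lower in CSC-rich cells: all 22 measured members of the mitosis and G2/M list passed the test, with a median log2 difference of -3.68. Among them were AURKB, a kinase of the chromosomal passenger complex, with a log2 difference of -5.24 ± 0.51 (SE, n = 3 arrays per population), KIF20A, a mitotic kinesin, at -5.01 ± 0.34, BIRC5 (survivin) at -4.72 ± 0.34, CCNB2 (cyclin B2) at -4.51 ± 0.32 and UBE2C, which works with the anaphase-promoting complex, at -4.24 ± 0.39. KIF20A, BIRC5, CCNB2 and UBE2C were thus 32.3-, 26.3-, 22.8- and 18.9-fold lower, and AURKB was detected on 2 of the 3 CSC-rich arrays. The list median was -3.92, -3.23 and -3.55 in untreated, scramble-treated and PNAs-A15-treated cells. In limma's camera test the list had an adjusted p of 1.8e-31, and adjusted p = 0.45 with an estimated correlation (unadjusted 0.038).

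Other genes of cell division and DNA synthesis were also lower. The centromeric histone CENPA (-4.84), the kinesins KIF4A (-4.69) and KIF2C (-4.32), the transcription factor FOXM1 (-4.39), PIMREG (-4.24) and thymidine kinase TK1 (-4.19 ± 0.40) were among the 12 lowest genes past the threshold. FOXM1 and KIF2C were detected on 2 of the 3 CSC-rich arrays, and CENPA and KIF4A on 1. CDCA3 was not detected on any CSC-rich array and was at least 22.1-fold lower there, with limma's adjusted p at 0.0073. Of 20 measured genes of DNA replication and S phase, 4 were lower past the threshold and 15 when adjusted over the list alone. The 4 were TK1, the replication licensing and helicase factors CDC45 (-3.35 ± 0.34) and CDT1 (-2.50 ± 0.36), and GINS2 (-2.14 ± 0.32). The list median was -1.44 (camera adjusted p 1.6e-10, and adjusted p = 0.45 with an estimated correlation). Of 18 measured oxidative phosphorylation genes, 17 were lower in CSC-rich cells and none passed the threshold alone, UQCRC1 lying at -1.45 ± 0.37 and SDHA at -1.25 ± 0.35. Their median was -0.59 (camera adjusted p 0.00083, and adjusted p = 0.45 with an estimated correlation).

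Of the genes highest in CSC-rich cells, the secreted glycoprotein STC1 was 23.0-fold higher (log2 4.52 ± 0.39), the secreted proteoglycan ESM1 had a fitted log2 difference of 5.21 ± 0.58 and HSPA6, an inducible member of the Hsp70 family, 4.49 ± 0.62. ESM1, HSPA6, FOS, SEMA6A and TMEM45A were detected on 2 of the 3 parental arrays, not on that of PNAs-A15, and H4C8, SVEP1 and IL13RA2 on 1, so their fitted values rest in part on levels below detection. The mitophagy receptor BNIP3L followed at 3.45 ± 0.38, with the histone gene H4C8 (3.58), SVEP1 (3.37), the decoy receptor IL13RA2 (3.29), AMDHD1 (3.27), SEMA6A (3.23), ANKRD29 (3.19) and TMEM45A (3.17). Adjusted p-values of these genes in limma's fit lay between 0.0083 and 0.036.

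By list, 19 of 22 immediate early genes were higher in CSC-rich cells, 2 past the threshold and 9 when adjusted over the list alone. FOS, a transcription factor of the early growth response, was 3.23 ± 0.54 higher and the phosphatase DUSP1 2.89 ± 0.35 higher, whereas JUN, at 1.80 ± 0.36, missed the threshold (adjusted p 0.061 in limma). The list median was 0.97 (camera adjusted p 1.5e-05, and adjusted p = 0.45 with an estimated correlation). Among 24 genes of hypoxia and glycolysis, BNIP3L and ANKRD37 (2.51 ± 0.32) passed the threshold, and 6 did when adjusted over the list alone. P4HA1 lay at 2.48 ± 0.62 and PFKFB4 at 1.76 ± 0.35. The list median was 0.83 (camera adjusted p 0.00069, and adjusted p = 0.45 with an estimated correlation). It was 0.73 on the PNAs-A15 pair, where it turned to -0.09 with median scaling.

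All 6 measured neuroendocrine markers were higher in CSC-rich cells, 1 past the threshold and 4 when adjusted over the list alone. INSM1, a transcription factor of neuroendocrine cells, was 2.33 ± 0.41 higher, beside ENO2 at 1.56 ± 0.37 and NCAM1 at 1.39 ± 0.37. The median was 1.18 (camera adjusted p 0.0047, and adjusted p = 0.45 with an estimated correlation). Heat shock proteins stood at the threshold itself (median 0.41, camera adjusted p 0.05, and adjusted p = 0.72 with an estimated correlation), and their median was 0.01 in untreated cells and 0.95 on the PNAs-A15 pair; the list lost its call on unnormalized signals. Only HSPA6 of their 16 members passed.

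Over all 6 arrays, markers of stem cells did not pass as a group. Of 16 measured members 8 were higher and 8 lower, with a median of -0.06 (camera adjusted p 0.58), and 3 passed when adjusted over the list alone, 1 higher and 2 lower. The list median was -0.32 in untreated cells (percentile 1.1), 0.34 with scramble (percentile 83.6) and -0.03 with PNAs-A15 (percentile 63.6); it kept its sign under all 3 scalings only in untreated cells. ID3, a target of BMP signalling, was lower past the threshold (-2.35 ± 0.40), while KLF4 lay at 1.67 ± 0.33 and the intermediate filament NES at -1.52 ± 0.33, with limma's adjusted p at 0.061 and 0.073. CD44 lay at 0.30 ± 0.34, SOX2 at 0.38 ± 0.37, ABCG2 at -0.45 ± 0.35 and ALDH1A1 at 0.06 ± 0.37, and other probes of CD44, SOX2 and ALDH1A1 disagreed with these values. PROM1, NANOG and POU5F1 were not detected on any array.

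In the NF-kB and inflammatory list, 3 of 14 genes passed the threshold (4 when adjusted over the list alone), all higher in CSC-rich cells, among them the chemokine CCL20 (2.96 ± 0.38) and the inhibitor TNFAIP3 (1.76 ± 0.32); the list did not pass (median 0.17, adjusted p 0.17). The histone list held 2 genes higher past the threshold, H4C8 and H2BC5 (3.03 ± 0.47), and 1 lower, H4C3 (-2.07 ± 0.32), with a list median of 0.67 (adjusted p 0.43) and 3 higher and 2 lower when adjusted over the list alone. Single members past the threshold in other lists were AXL, a receptor kinase among the mesenchymal markers (-2.64 ± 0.44; list median 0.20, adjusted p 0.61), DDIT3 in the unfolded protein and ATF4 list (-2.42 ± 0.37, detected on 2 of the 3 CSC-rich arrays; median -0.23, adjusted p 0.61), RPS23 among ribosomal proteins (1.94 ± 0.33; median 0.03, adjusted p 0.54) and ID3 among TGF-beta and BMP targets (median 0.45, adjusted p 0.83). Adjusted over the list alone, 2 genes were higher and 2 lower in the mesenchymal list and in the TGF-beta and BMP list, 0 and 1 in the unfolded protein list, and 1 and 0 among ribosomal proteins.

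The remaining lists held no gene past the threshold and none passed camera. Their medians and adjusted p-values were -0.37 and 0.38 for epithelial markers, -0.12 and 0.47 for p53 targets, -0.32 and 0.43 for apoptosis regulators, 0.26 and 0.88 for cholesterol biosynthesis, and -0.05 and 0.75 for fatty acid synthesis. Serine and glycine metabolism had -0.47 and 0.061 (0.0096 on unnormalized signals, past the threshold), NRF2 and oxidative stress -0.13 and 0.54, metallothioneins -0.59 and 0.43, and interferon-stimulated genes 0.00 and 0.96. Wnt, Notch and Hedgehog targets had 0.22 and 0.76, extracellular matrix 0.12 and 1, lysosome and autophagy 0.09 and 0.62, and ABC transporters 0.29 and 0.62. Of markers of other cells, immune markers had -0.42 and 0.76, and fibroblast and endothelial markers 0.72 and 0.54. The median of these 5 fibroblast and endothelial genes was 1.14 in untreated cells and 1.70 with scramble (both at percentile 99.8), and -0.23 with PNAs-A15 (percentile 46.5). Of the lung airway list only AGER was measured, at -0.12 ± 0.36. Adjusted over the list alone, 1 gene was lower among epithelial markers, p53 targets and Wnt, Notch and Hedgehog targets each, 2 were higher and 3 lower among apoptosis regulators, 1 was higher and 1 lower among fibroblast and endothelial markers, and 0 passed in the other lists here. The medians for extracellular matrix, lysosome and ribosomal genes turned below 0 with median scaling, and that of interferon-stimulated genes changed sign between scalings.

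In total, 279 of 12101 genes passed an adjusted p of 0.05 in limma's additive fit, 101 higher and 178 lower in CSC-rich cells, and 2291 had an unadjusted p under 0.05. The count was 2324 without either PNAs-A15 array, 419 without either untreated array and 87 without either scramble array, 3633 without the parental PNAs-A15 and CSC-rich scramble arrays, and 0 with no filter on dim probes. Median scaling gave 392 higher and 406 lower, and unnormalized signals 2 higher and 19 lower. Between single arrays, 811 genes were at least 2-fold higher and 715 lower in untreated CSC-rich cells, 1925 and 1597 with scramble, and 2240 and 2425 with PNAs-A15. These splits depended on the scaling: with median scaling they were 817 and 747, 2464 and 1341, and 1553 and 4238, and on unnormalized signals 347 and 474, 467 and 1908, and 2800 and 606. The median of all genes was 0.14 on the scramble pair (0.32 with median scaling, -0.23 on unnormalized signals) and -0.14 on the PNAs-A15 pair (-0.60 and 0.32).

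**Figure D1:**
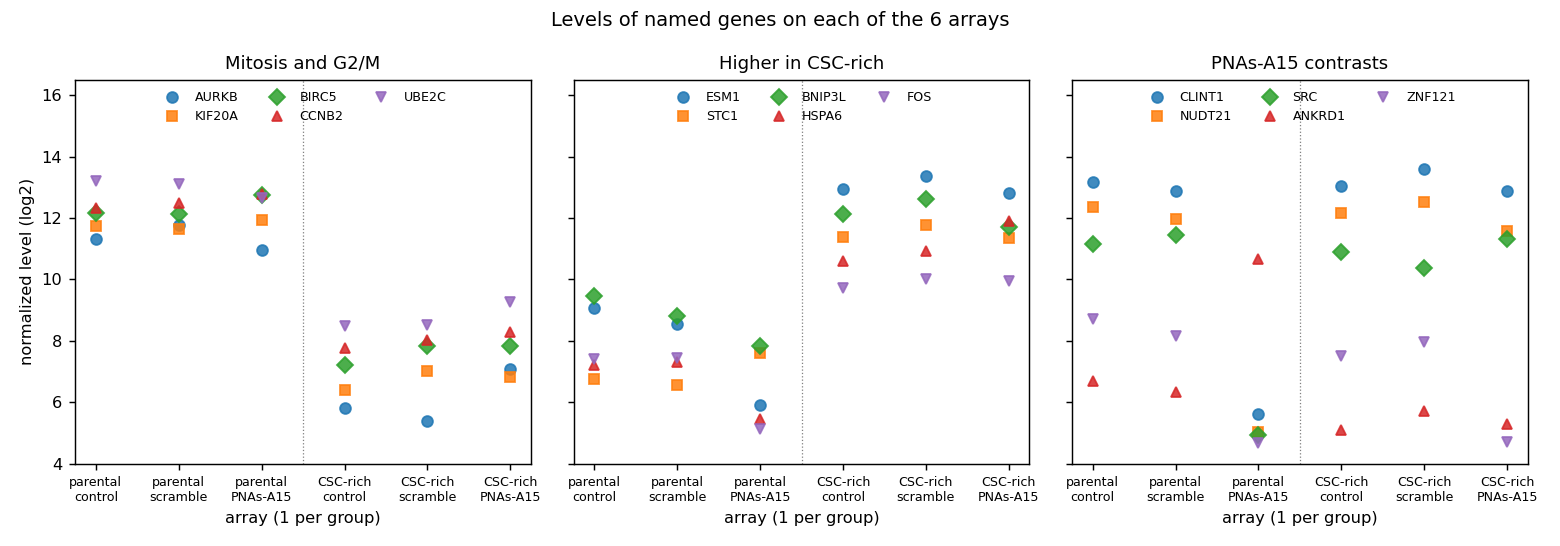
Normalized log2 level (vertical axis) of 15 named genes on each of the 6 arrays (horizontal axis), 1 point per gene and array, with mitotic genes on the left, genes higher in CSC-rich cells in the middle and genes of the PNAs-A15 contrasts on the right. AURKB lay between 10.95 and 11.76 on parental arrays and between 5.39 and 7.08 on CSC-rich arrays, and CLINT1 lay at 5.63 on the parental PNAs-A15 array alone.

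The second comparison set PNAs-A15 against the scramble control after 6 h. In parental cells the PNAs-A15 array differed from scramble at least 2-fold in 4577 genes (37.8%), 2538 higher and 2039 lower, against 81 genes between scramble and untreated cells. The deepest differences lay in probes bright on the other arrays, read by 1 probe per gene. CLINT1, a clathrin adaptor, was at least 113-fold lower and not detected, as were the mRNA 3' end processing factor NUDT21 (at least 60.2-fold), the tyrosine kinase SRC (at least 42.1-fold) and the mitochondrial ribosomal protein MRPS35 (at least 37.8-fold), and the splicing factor HNRNPH1 lay at -6.74 on the log2 scale. The highest differences were in ANKRD1 (4.34), ZSWIM4 (4.08) and PCED1B (3.64), with ADAMTS4 at least 7.67-fold and RAPGEF3 at least 9.68-fold higher. In CSC-rich cells CLINT1, NUDT21, HNRNPH1, SRC and MRPS35 differed by -0.72, -0.93, -0.11, 0.96 and 0.17.

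Among the lists, heat shock proteins were lower on the parental PNAs-A15 array, with a median of -0.85 (percentile 0.0 among 10000 random lists). HSPA1B lay at -3.45, the cochaperone DNAJB1 at -3.97 and HSP90AB1 at -1.78. Cholesterol biosynthesis genes had a median of -0.63 (percentile 0.5), with 8 of 19 at least 2-fold lower, among them the sterol sensor partner INSIG1 at -3.20 and lanosterol synthase LSS at -2.02. DNA replication genes had a median of -0.62 (percentile 0.4), with the ribonucleotide reductase subunit RRM2 at least 37.9-fold lower and UHRF1 at -4.45, whereas the mitosis list lay at 0.06 (percentile 31.3). Interferon-stimulated genes had a median of 0.99 (percentile 99.2), with IFITM1 at 3.01, IFI6 at 2.49 and IFIT1 at 2.23. Of their 19 measured members 9 were at least 2-fold higher and 3 lower. NRF2 and oxidative stress genes had a median of -0.48 (percentile 1.0), with 7 of 18 at least 2-fold lower and 1 higher. Mesenchymal markers had -0.63 (percentile 1.9), with 4 of 13 lower and 2 higher. Both medians turned above 0 with median scaling (0.26 and 0.20). The unfolded protein and ATF4 list, at 0.53 (percentile 95.3), lay inside the middle 95% of random lists. It held DDIT3 at 2.01, CEBPB at 2.06 and TRIB3 at 1.98, with 6 of 20 members at least 2-fold higher and 2 lower. The 5 measured immune cell markers had a median of 1.53 (percentile 99.8), including LYZ, at least 5.05-fold higher, and CD14 and CD68, both at 1.53.

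These parental values rest on a single array that stood apart from all others, with each gene read by 1 probe. Among 2040 genes with 2 bright probes, the probes differed at least 4-fold in 470 (23.0%) for PNAs-A15 minus scramble. MCM4 of the replication list gave -0.61 and -5.91. The gene and list values above need not hold for whole transcripts. The split of higher and lower genes depended on the scaling: against scramble it was 4577 higher and 1390 lower with median scaling, and 231 higher and 3196 lower on unnormalized signals. The median of all genes moved from 0.20 to 0.68 with median scaling and to -0.43 on unnormalized signals; the interferon and mitosis medians changed sign on unnormalized signals (-0.04 and -0.45), and the heat shock, cholesterol, replication, unfolded protein and immune medians kept theirs but not their size. With median scaling and then on unnormalized signals these were -0.21 and -1.28 for heat shock, -0.27 and -1.33 for cholesterol, -0.06 and -1.16 for replication, 1.39 and 0.15 for the unfolded protein list, and 1.64 and 0.27 for immune markers.

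In CSC-rich cells 1148 genes (9.49%) differed at least 2-fold between PNAs-A15 and scramble, 773 higher and 375 lower, against 456 between scramble and untreated cells and 60 between PNAs-A15 and untreated cells. With median scaling the split turned to 560 higher and 730 lower, and on unnormalized signals it was 644 higher and 3 lower. The 5 highest were NSUN5P1 (at least 3.68-fold), the translation factor EEF1G (2.92), the thioesterase ACOT1 (at least 5.14-fold), the NADPH oxidase subunit CYBA (2.74) and the proteasome subunit PSMC4 (at least 3.86-fold). The 5 lowest were ZNF121 (at least 4.72-fold), GSDMA (-1.97), the primase subunit PRIM2 (at least 2.23-fold), KLLN (-1.87) and CRIPTO3 (at least 2.02-fold). Against the untreated array, EEF1G lay at 0.64, ACOT1 at 0.85 and CYBA at 0.90. Stem cell markers had a median of -0.48 (percentile 0.6), with SOX2 at -0.99 and ALDH1A3 at least 1.8-fold lower. Oxidative phosphorylation genes had 0.14 (percentile 98.0) and cytosolic ribosomal proteins 0.11 (percentile 98.2), which turned to -0.16 and -0.14 with median scaling. Against untreated cells the stem cell median was -0.15. The median of all genes was -0.10 here, -0.27 with median scaling and 0.11 on unnormalized signals.

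**Figure D2:**
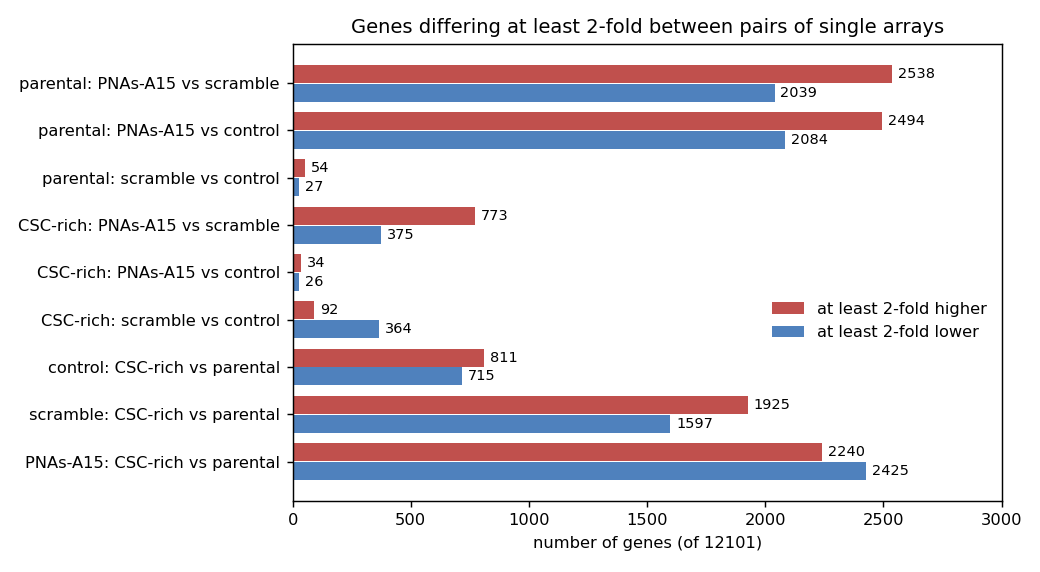
Number of genes (horizontal axis, of 12101 tested) at least 2-fold higher (red) or lower (blue) in each pair of single arrays, with the array named first set against the second. The parental PNAs-A15 array gave 2538 higher and 2039 lower against scramble, and PNAs-A15 against untreated CSC-rich cells gave 34 and 26; the split of higher and lower genes shifts with the scaling.

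Between the populations, 26 genes were at least 2-fold higher in both and 116 at least 2-fold lower in both, against 162.1 and 63.2 if the populations were independent, and 365 differed at least 2-fold in opposite directions. With median scaling 33 were higher and 211 lower in both, against 211.8 and 83.9, and on unnormalized signals 0 and 2, against 12.3 and 0.8, with 402 in opposite directions. ZNF121, a zinc finger gene, was not detected on either PNAs-A15 array and was at least 4.28-fold lower than scramble in parental and 4.72-fold lower in CSC-rich cells. Of the other genes lowest in both, 7 were not detected on the parental PNAs-A15 array. Their parental bound and CSC-rich log2 difference were at least 5.85-fold and -1.74 for HAUS5, 2.89-fold and -1.65 for PCGF5, 1.54-fold and -1.70 for SMCHD1, 1.78-fold and -1.50 for the kinase JAK2, 2.0-fold and -1.42 for SLAIN1, 7.64-fold and -1.41 for ZFX, and 6.44-fold and -1.41 for the 3' end processing factor CPSF6. CKAP2 (-3.11, -1.36) and SNX10 (-1.36, -1.40), parental value first, were detected throughout. Of the genes highest in both, POLD4 (1.35, 1.45), NICOL1 (1.26, 1.36) and CUL9 (1.35, 1.25) were detected throughout. The others were not detected on the CSC-rich scramble array, and their parental log2 difference and CSC-rich bound were 2.01 and at least 2.04-fold for the stress-response transcription factor DDIT3, 1.86 and 1.85-fold for the repair polymerase POLL, 1.95 and 2.45-fold for the NF-kB subunit NFKB2, 1.30 and 2.73-fold for WDR24, 1.71 and 2.21-fold for the DNA glycosylase MPG, and 2.04 and 1.72-fold for CITED4. LIN7B, detected on neither scramble array, was at least 5.16-fold and 1.72-fold higher. The parental values of WDR24 and NICOL1 were -0.02 and -0.03 on unnormalized signals.

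None of these differences passed the test: limma's additive fit called 0 genes, with 490 at an unadjusted p under 0.05 and a lowest adjusted p of 0.786, and camera called 0 lists, with 1 at an unadjusted p under 0.05. Across genes, which are not independent replicates, the PNAs-A15 minus scramble differences of the populations had a Pearson r of -0.08 and a Spearman rho of -0.07, and 41.8% of the 2278 genes at least 1.5-fold apart in both had the same sign. The count of genes called rose to 85, all lower, with median scaling. It also rose without either untreated array and most without the CSC-rich PNAs-A15 array. In the last case PNAs-A15 is read from the parental array alone, which stood apart, so those calls are no evidence of a PNAs-A15 effect. The median of all genes was 0.12 in the fit, 0.27 with median scaling and -0.12 on unnormalized signals.

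**Figure D3:**
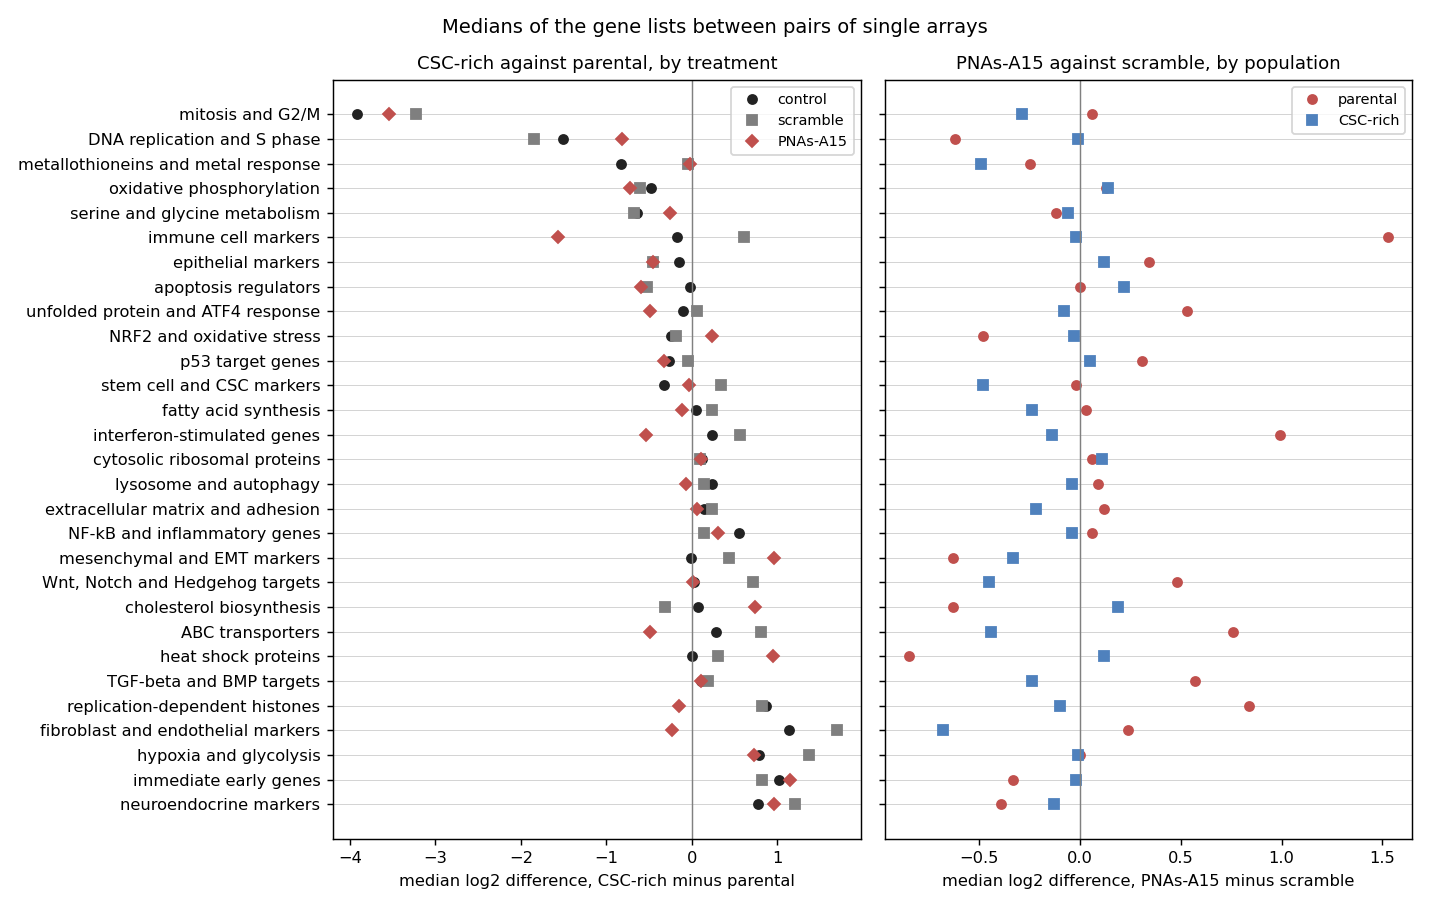
Median log2 difference (horizontal axes) of the 29 gene lists with at least 3 measured members (vertical axis), for CSC-rich minus parental arrays at each treatment on the left and for PNAs-A15 minus scramble in each population on the right, 1 point per list and array pair. The mitosis list lay at -3.92, -3.23 and -3.55 between populations, and the heat shock list at -0.85 for PNAs-A15 in parental cells; list medians for parental PNAs-A15 shift with the scaling, and that of interferon-stimulated genes changed sign on unnormalized signals.

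The third comparison set scramble against untreated cells, the level of change without PNAs-A15. In parental cells 54 genes were at least 2-fold higher and 27 lower, and in CSC-rich cells 92 higher and 364 lower. With median scaling these were 73 and 40, and 177 and 236, and on unnormalized signals 14 and 0, and 0 and 280. Of the genes highest in both populations, LLGL1 (0.67 in parental, 0.77 in CSC-rich) and RDM1 (0.68, 0.64) were detected on the arrays compared, whereas only bounds hold for SIAE (at least 1.22- and 1.48-fold), SEMA4A (1.14- and 1.41-fold) and CSC-rich MYH14 (2.69-fold, with 0.72 in parental cells). Of the lowest, RBM48 lay at -1.01 and -0.88 and SNN at -0.75 and -0.75, and bounds hold for MIR1282 (at least 1.98- and 2.48-fold), POTEG (1.81- and 1.14-fold) and MICALL2 (1.36- and 1.07-fold). Cholesterol biosynthesis genes were lower (18 of 19, median -0.22, camera adjusted p 1.7e-05), as were histones (8 of 9, median -0.27, adjusted p 0.004), and mitosis genes were higher (20 of 22, median 0.14, adjusted p 0.025), each with adjusted p = 0.68 with an estimated correlation. The CSC-rich scramble array carried the rise of mitosis genes (0.50, against -0.14 in parental cells), though only at 0.06 on unnormalized signals. Cholesterol lay at -0.30 (percentile 0.2) in CSC-rich and -0.08 (percentile 25.9) in parental cells, and histones at -0.25 and -0.18. With median scaling these were -0.07 and -0.16 for cholesterol and -0.03 and -0.23 for histones. On unnormalized signals they were -0.41 and -0.02, and -0.45 and -0.09. Which population carried the fall of these 2 lists thus depended on the scaling.

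No gene passed limma's fit here, and 1 had an unadjusted p under 0.05. Across genes the scramble minus control differences of the populations ran opposite (Pearson r -0.51, Spearman rho -0.52), and 9.20% of the 402 genes at least 1.5-fold apart in both had the same sign. In CSC-rich cells the median of all genes was 0.08, 0.24 with median scaling and -0.15 on unnormalized signals, and the mitosis list in the fit lost its call under both.

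The last comparison set PNAs-A15 against untreated cells. Cholesterol biosynthesis genes were lower, 15 of 19, with a median of -0.56 (camera adjusted p 0.0091, and adjusted p = 0.99 with an estimated correlation); the median was -0.79 in parental (percentile 0.2) and -0.32 in CSC-rich cells (percentile 0.0). The call held under the other scalings, with a median of -0.27 with median scaling and -0.75 on unnormalized signals. In CSC-rich cells, scramble alone gave a cholesterol median of -0.30 (percentile 0.2) against untreated cells. Other lists also lay far out by percentile without passing camera. In parental cells these included heat shock proteins (-1.08, percentile 0.0) and interferon-stimulated genes (1.09, percentile 99.8, but 0.03 on unnormalized signals). In CSC-rich cells fatty acid synthesis lay at -0.25 and histones at -0.40, both at percentile 0.1. Against scramble, the CSC-rich cholesterol median was 0.19 (percentile 96.9), in the other direction, but 0.02 with median scaling and 0.40 on unnormalized signals. INSIG1 lay at -3.96 in parental and -0.45 in CSC-rich cells, and LSS at -1.96 and -0.32. Of the genes lowest in both, the kinase TAOK1 lay at -3.0 in parental and -0.93 in CSC-rich cells. The others were not detected on the parental PNAs-A15 array. ZNF121, ZNF679, SIKE1 and MIR7-1 were not detected on the CSC-rich one either and were at least 6.29- and 3.42-fold, 1.49- and 1.81-fold, 1.11- and 1.69-fold, and 1.15- and 1.26-fold lower in parental and CSC-rich cells. The parental bound and CSC-rich log2 difference were at least 2.34-fold and -1.21 for REEP3, 1.26-fold and -1.21 for COL24A1, 2.02-fold and -1.02 for SUDS3, 4.26-fold and -0.92 for MAP3K21, and 1.09-fold and -0.91 for ARHGAP18. Of the highest, parental value first, PGM5-AS1 (2.19, 1.20), SSX3 (1.60, 1.09), HSPA7 (1.08, 1.14), FSTL3 (1.47, 1.0), S100A14 (1.71, 0.97) and SUSD5 (1.06, 0.89) were detected on the arrays compared. NFKB2 and FKBP10 were not detected in untreated parental cells (at least 10.3- and 2.37-fold, with 1.08 and 1.23 in CSC-rich cells), SHOX2 not in untreated CSC-rich cells (1.25 in parental cells, at least 2.25-fold), and the receptor ERBB3 in neither (at least 1.93- and 1.37-fold). In total 2494 genes were at least 2-fold higher and 2084 lower in parental cells, and 34 and 26 in CSC-rich cells; with median scaling these were 4370 and 1449, and 49 and 30, and on unnormalized signals 320 and 2815, and 1 and 4. The parental values of HSPA7 and SUSD5 were 0.00 and -0.04 on unnormalized signals.

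Limma's fit called 0 genes, with 450 at an unadjusted p under 0.05 and a lowest adjusted p of 0.752. Across genes the populations correlated at a Pearson r of 0.18, and 60.8% of the 454 genes at least 1.5-fold apart in both had the same sign. The count was 54 with median scaling. It also rose without the CSC-rich untreated array and most without the CSC-rich PNAs-A15 array. In these fits untreated cells or PNAs-A15 are read from the parental array alone. The median of all genes was 0.11 in the fit, 0.34 with median scaling and -0.18 on unnormalized signals.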

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

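The tests of array scaling, of serum, of a response shared by both populations and of probe noise on the CSC-rich scramble array, the exchange of labels, the values with undetected signals raised, and the repeat of the CSC-rich count without 2 arrays, were chosen only after the results were seen.

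Named genes were singled out where PNAs-A15 and scramble differed at least 2-fold in opposite directions in the 2 populations, 23 genes in all. With 1 array per group the difference between populations was not tested. It is given as the CSC-rich minus the parental log2 difference. The value was positive for PGAM1 (6.54), NSUN5P1 (5.72), BAX (5.57), EEF1G (5.31), ACOT1 (4.57), LTBP3 (4.31), CYBA (3.80), KRT19 (3.60), ATP6V0D1 (3.38), JUNB (3.11), EBP (2.89), CTSA (2.87), JUP (2.23) and FTL (2.22). It was negative for GSDMA (-5.23), ADAMTS4 (-5.12), KLLN (-4.97), LYZ (-4.22), PRIM2 (-3.79), IFIH1 (-3.06), MYH14 (-3.02), EGLN3 (-2.79) and MT1G (-2.74). Of these genes, 9 were not detected on at least 1 of the 4 arrays, so their values hold levels below detection. With those raised to the lowest detected signal they became 4.43 for NSUN5P1, 4.15 for ACOT1, 2.33 for LTBP3, 1.84 for JUNB, -3.33 for ADAMTS4, -3.05 for LYZ, -3.04 for PRIM2, -2.99 for MYH14 and -2.62 for EGLN3, and 19 of the 23 still differed at least 2-fold in opposite directions, ADAMTS4, LYZ, JUNB and LTBP3 not. Against the untreated array, these genes lay between -0.85 and 1.0 on the CSC-rich PNAs-A15 array. For PNAs-A15 against scramble no gene list lay above the range that holds the middle 95% of random lists in 1 population and below it in the other. Nearest were heat shock proteins at 0.0 in parental and 96.3 in CSC-rich cells (medians -0.85 and 0.12) and cholesterol biosynthesis at 0.5 and 96.9 (-0.63 and 0.19). With median scaling the CSC-rich medians of these lists were -0.15 and 0.02, so the opposite direction was lost or nearly so. For scramble against untreated cells, outside that comparison, stem cell markers lay at percentile 0.2 in parental and 99.6 in CSC-rich cells and fibroblast and endothelial markers at 1.5 and 98.8. Groups of 1 array allowed no search for outlying samples within groups.

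Mitosis and replication genes were lower in CSC-rich cells. Unnormalized signals argued against array scaling, since the mitosis median stayed at -2.81 or lower in every treatment pair and the replication median at -1.46 or lower in untreated and scramble-treated cells under 3 scalings; on the PNAs-A15 arrays scaling stays open for replication genes, at -0.34 on unnormalized signals and -1.44 with median scaling. Serum, given to parental cells alone, stays open: a medium poor in lipoproteins would raise cholesterol genes, and their median was 0.74 on the PNAs-A15 arrays (0.27 with undetected values raised to the lowest detected signal) but -0.31 on the scramble and 0.08 on the untreated arrays (with median scaling 0.04, -0.03 and 0.10), which neither meets nor excludes it. The 279 genes came from 1 of the 10 splits of the 6 arrays into 3 and 3, the highest of the other splits giving 0, and 10 splits are too few for a share under 0.05. The spheroid-grown population itself, which the design names, was not separated from its medium.

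The parental PNAs-A15 array stood apart from all others. A dim array was argued against, because 26.8% of the 3026 genes brightest on the other 5 arrays differed at least 2-fold from scramble, against at most 5.0% in pairs within a population without this array. A sample of other cells stays open: 38 genes at a log2 level of 10 or more on the other 5 arrays were not detected here, against 0 for any other array, which a strong response or damaged RNA would give too. Noise of single probes stays open, since the brightest 2 probes of a gene correlated at 0.26 across genes, between the bounds set beforehand. A response to PNAs-A15 in parental cells cannot be told apart from a fault of this array without a replicate.

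The CSC-rich scramble array stood apart from the other CSC-rich arrays. Noise of single probes as the whole cause was argued against, by a bound set after the value had been seen. Scramble minus control correlated at -0.51 between populations that share no array, although 2 probes of a gene correlated at only 0.43. Parental scramble minus control correlated at 0.62 with CSC-rich PNAs-A15 minus scramble, but this is no separate support. The CSC-rich scramble array is part of both CSC-rich differences, and the untreated and PNAs-A15 CSC-rich arrays correlated at 0.992. The 0.62 thus largely repeats the -0.51 with its sign turned. The lower share of probes detected on the CSC-rich scramble array was not tested as a cause. A PNAs-A15 response shared by both populations would not set the scramble array apart, so its test does not bear on this pattern. In CSC-rich cells PNAs-A15 differed from untreated in 60 genes and scramble in 456. Whether a shared response exists stays open. PNAs-A15 minus scramble correlated between the populations at -0.08, which rests on this array, and PNAs-A15 minus control at 0.18. More genes were at least 2-fold lower than scramble in both (116) than independence gives (63.2), but fewer higher (26 against 162.1). Against untreated cells 6 were lower (4.5) and 8 higher (7.0). Exchanged labels of the untreated and scramble CSC-rich arrays stay open for want of a test, since the exchange only turns the correlation of scramble minus control between populations from -0.51 to 0.51. A response of CSC-rich cells to scramble was not tested, for want of a replicate.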

How the results depend on the processing

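The count without the parental PNAs-A15 and CSC-rich scramble arrays, the counts with undetected values raised and the correlation with median scaling were chosen only after the results were seen. No paired analysis was possible because each group has 1 array and the labels carry no replicate numbers; the treatment block of the fit sets the arrays of a treatment side by side, and the count without it is given below. Leaving out an array leaves 1 residual degree of freedom and assumes that the lone array of a treatment varies like the others; either array of a treatment then gives the same value for the populations.

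CSC-rich against parental cells (279 genes) gave 798 with median scaling, 547 with a trended robust variance and 638 without the treatment block. It gave 3633 without the 2 arrays that stood apart, also without the treatment block. The count was 21 on unnormalized signals and 0 with no filter on dim probes (2954 at an unadjusted p under 0.05). Leaving out single arrays gave 87 to 2324, and the cause was not tested. PNAs-A15 against scramble (0 genes) gave 85 with median scaling and 0 to 3459 on leaving out single arrays; against untreated cells (0 genes) it gave 54 and 0 to 3770; the cause was not tested. Scramble against untreated cells stayed at 0. Lists past camera fell from 7, 3 and 1 for CSC-rich, scramble and PNAs-A15 against untreated to 0 with estimated correlations. That form rests on the 2 residual degrees of freedom. Correlation between genes does not account for the loss of the hypoxia list between populations, where it was estimated at -0.04. The unadjusted camera p of that list rose from 9.5e-05 to 0.049. Unnormalized signals gave 6 lists for scramble, and the cause of that was not tested.

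Counts at least 2-fold, with a threshold of 1.5-fold and then with detection on all arrays, were 7200 and 2858 for parental PNAs-A15 against scramble, 902 and 11 for parental scramble against untreated, 7299 and 2877 for parental PNAs-A15 against untreated, 3846 and 580 for CSC-rich PNAs-A15 against scramble, 2316 and 194 for CSC-rich scramble against untreated, and 719 and 8 for CSC-rich PNAs-A15 against untreated. Between populations they were 3778 and 933 untreated, 6299 and 2233 with scramble, and 7434 and 2911 with PNAs-A15. The 1.5-fold counts follow from the lower threshold. Detection on all arrays left 8322 of the 12101 genes, but fewer genes do not account for all of the fall. Parental scramble against untreated fell from 81 genes to 11, and CSC-rich PNAs-A15 against untreated from 60 to 8. Much of those counts thus came from genes not detected on all arrays. With an offset of 50 and then on unnormalized signals, the counts were 8 and 14 for parental scramble against untreated, 476 and 647 for CSC-rich PNAs-A15 against scramble, 114 and 280 for CSC-rich scramble against untreated, 5 and 5 for CSC-rich PNAs-A15 against untreated and 938 and 821 between untreated populations; the offset leaves more background in dim probes, while unnormalized signals drop background correction and scaling together, and which of these caused the change was not tested. Raising undetected values to the lowest detected signal gave 4190 (from 4577) for parental PNAs-A15 against scramble and 4216 (from 4578) against untreated. The smaller counts fell by a larger share. Parental scramble against untreated gave 67 (from 81). In CSC-rich cells PNAs-A15 against scramble gave 985 (from 1148), scramble against untreated 333 (from 456) and PNAs-A15 against untreated 41 (from 60).

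The correlation of PNAs-A15 minus scramble between populations (-0.08) was -0.09 with median scaling, -0.06 with an offset of 50, -0.06 on unnormalized signals, -0.12 with detection on all arrays and turned to 0.18 against untreated cells; the cause was not tested. The split of higher and lower genes between single arrays turned in direction with the scaling in every pair but scramble against untreated cells of either population: on unnormalized signals for parental PNAs-A15 against scramble (2538 and 2039, then 231 and 3196) and untreated (2494 and 2084, then 320 and 2815), CSC-rich PNAs-A15 against untreated (34 and 26, then 1 and 4) and the populations untreated (811 and 715, then 347 and 474), with scramble (1925 and 1597, then 467 and 1908) and with PNAs-A15 (2240 and 2425, then 2800 and 606), and with median scaling for CSC-rich PNAs-A15 against scramble (773 and 375, then 560 and 730). Of the named genes between populations, 266 gene and setting pairs kept their call and 55 lost it, 24 of them with no filter and 19 on unnormalized signals. For PNAs-A15 against scramble over both populations, 23 gene and setting pairs gained a call and 241 did not. In single arrays, 43 pairs moved by at least 0.5 on the log2 scale and 41 did not in parental cells, and 19 moved and 65 did not in CSC-rich cells. Signal over background limits probes near log2 levels of 5, which have bounds only.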

Other observations

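The splicing factor, nucleoporin and 3' end processing lists, the genes singled out over both control arrays, and the repeat of a probe-gap correlation with the untreated parental array were chosen only after the results were seen.

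Genes of RNA handling were among those lower on the parental PNAs-A15 array. Of 29 hnRNP and SR splicing factors, 20 were at least 2-fold lower than scramble and 0 higher, with a median of -1.41 (percentile 0.0 of random lists), and 21 were lower against untreated cells (median -1.55). In CSC-rich cells their median was -0.33 against scramble (percentile 1.6), with 3 at least 2-fold higher and 0 lower, and 0 of the 29 differed at least 2-fold between PNAs-A15 and untreated cells, with a median of -0.10 (percentile 6.0). Nucleoporins had a median of -0.69 (percentile 0.1) against scramble and -0.26 (percentile 5.2) against untreated parental cells. These percentiles are no independent support, because the lists were chosen after low genes such as HNRNPH1 had been seen on this array. No other scaling is given for these medians. The heat shock median of parental PNAs-A15 against scramble moved from -0.85 to -0.21 with median scaling. Factors of mRNA 3' end processing, listed because NUDT21 and CPSF6 were low, did not move as a group: the median of 18 measured members was 0.10 (percentile 38.2), with 6 at least 2-fold lower and 3 higher.

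Only 3 genes differed at least 2-fold in 1 direction from both control arrays in both populations: NFKB2 was higher, and ZNF121 and REEP3 were lower. REEP3 was not detected on the parental PNAs-A15 array, where its bound against scramble was only 1.45-fold. Over both populations ZNF121 was at least 4.5-fold lower than scramble (limma's adjusted p 0.79) and at least 4.64-fold lower than in untreated cells. Its log2 level was 4.66 and 4.69, below detection, on the PNAs-A15 arrays and between 7.51 and 8.70 on the other 4, read by 1 probe.

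Probes of a gene often disagreed on the parental PNAs-A15 array. Among 2040 genes with 2 bright probes, 470 (23.0%) differed at least 4-fold between probes in PNAs-A15 minus scramble, against 0 in scramble minus control of the same cells. In 509 genes at least 1 probe was 4-fold or more lower, and in 288 of them the other probe stayed within 2-fold. KPNA2 gave -5.93 and 0.89, CRTAP -6.28 and 0.45, and BUB3 0.28 and -6.09. An effect of PNAs-A15 on parts of transcripts in both populations was argued against: the gap between probes, PNAs-A15 minus control, correlated between populations at 0.01. A fault of RNA or labelling shared with the CSC-rich scramble array may account for part of the gap, which correlated at 0.33 with that of CSC-rich scramble minus control. The value just passed the bound of 0.3 set beforehand and was 0.24 with the untreated parental array as the reference, and the parental scramble array itself gave -0.53, so part of it came from that array.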
